A study of Homo sapiens with 6 samples.

How the data were processed

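RNA was taken from Huh7 cells, a human hepatoma line grown in standard medium with serum and no treatment, per the labels' protocols. The labels give 3 libraries of unedited cells and 3 of cells in which RABIF was targeted with CRISPR/Cas9, and a genotype label placed each library in its group. Per the labels' protocols, total RNA was extracted with TRIzol, mRNA was isolated by poly(A) selection or ribosomal RNA removal without saying which, cDNA was made with random primers, and paired-end libraries were sequenced on an Illumina HiSeq. The labels name no batch, no strand marking and no molecular identifiers.

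One table of the whole series was used, with 57905 genes by Ensembl identifier and symbol. Per the file headers and the values, it holds for each library the authors' counts per gene, which are whole numbers without normalization, and the authors' FPKM, which are fragments per kilobase of exonic gene length and scaled by each library's total count. The deposited FPKM equal the deposited counts divided by exonic length and by the library's own total within 0.006 for 100% of genes, so both columns hold the same measurement. The genome build was GRCh37, per the submitters' processing notes. The aligner, the counter, the annotation release and the strand setting are not given in the sources used here. Reads shared by near-identical genes (globins, metallothioneins, aldo-keto reductases, histones) may therefore have been split or dropped, and genes that overlap on opposite strands cannot be told apart with certainty. Coordinates are those of the table. GENCODE 29, which is on another build, was used only to look up gene types and transcript GC content by stable gene identifier, and 97.5% of tested genes matched.

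Total counts were 16920556, 17868966 and 17732606 for the libraries labelled wild type and 16518838, 21127803 and 20929504 for those labelled knockout. A single count was worth 0.047 to 0.061 CPM. The 10 most abundant genes took 6.60% to 7.34% of counts and mitochondrial genes 4.47% to 4.73%. Within each group, every pair of libraries differed by more than sampling noise (chi-square per degree of freedom 2.31 to 3.64), so all were kept as separate samples. TMM factors lay between 0.994 and 1.01.

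The test was edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3) on the deposited counts, with TMM scaling, the filterByExpr filter by group, a design of group alone and Benjamini-Hochberg adjustment over 15445 genes. It was two-sided, with a threshold of 0.05. The standard error of a log2 fold change was its size divided by the square root of the quasi-likelihood F statistic. The tested genes held at least 99.8% of the counts of each library. The common biological coefficient of variation was 4.1%. Before the data were examined, 28 gene lists, the rule for named genes, the test and the alternatives were fixed, except where the text says otherwise. Each list was tested with limma 3.58.1's camera (preset correlation 0.01), with camera using a correlation estimated from the data, and with fry. These were adjusted over the 28 lists. Estimated correlations come from 6 libraries. Camera compares a list with other genes, and fry tests whether its members move, on balance, in 1 direction.

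The named genes were RABIF, the 10 largest rises and 10 largest falls among genes past the threshold, changed at least 2-fold, with no overlap between groups, a mean of at least 1 CPM in the higher group and a proper gene symbol, up to 4 members of each list with the smallest adjusted p, and a fixed set of glycolysis, mitophagy and Rab genes. Some genes that the rule names are not reported here. The rule left 423 candidates for the rises and 90 for the falls. A gene without counts in a group was given as a lower bound against 3 counts over the group, and a gene with 1 to 3 counts as a ratio of summed counts with an exact 95% interval.

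The lists were glycolysis, mitophagy, autophagy, lysosome, Rab GTPases and regulators, nuclear oxidative phosphorylation genes, the mitochondrial genome, mitochondrial dynamics and biogenesis, the tricarboxylic acid cycle, hypoxia, DNA replication, G2/M and mitosis, p53 targets, hepatocyte genes, cholesterol synthesis and uptake, fatty acid synthesis and storage, fatty acid oxidation, ATF4 targets, the unfolded protein response, interferon-stimulated genes, NRF2 targets, mesenchymal and matrix genes, heat shock and immediate early genes, ribosomal proteins, replication-dependent histones, and markers of blood, of fibroblast and endothelium and of other epithelial lines.

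The steps were tested on simulated counts for this comparison, drawn from the libraries' means and sizes with 200 of 15249 genes changed. Recovery was 62% at 1.25-fold, 80% at 1.5-fold, 90% at 2-fold and 96% at 4-fold, with 4.09% false calls. Of 200 random lists of 30 unchanged genes, 0.5% had a camera p under 0.05. Simulated genes were drawn independently of each other, so that share cannot speak for lists of correlated genes. The simulation also changed far fewer genes than the data, where 43.5% of tested genes passed the threshold.

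The alternatives were each library left out, the replicate number as a block, DESeq2's size factors or total counts in place of TMM, the DESeq2 1.42.0 Wald test, limma-voom, no filter or a filter of 1 CPM in 3 libraries, a 2-fold limit, and limma on log2(FPKM + 1) with FPKM of at least 1 in 3 libraries, with a pseudocount of 0.1, without the filter, after quantile normalization or rescaled to TPM. Fold changes on the log2(FPKM + 1) scale understate those of low genes.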

Results

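RNA was sequenced from Huh7 cells, an established human hepatocellular carcinoma line, with and without CRISPR/Cas9 targeting of RABIF. RABIF encodes a small zinc-binding protein that binds Rab GTPases, the switches of vesicle transport, in their nucleotide-free form. The series title places the gene in liver cancer progression, mitophagy and glycolysis, so the comparison asks which transcripts differ between the edited and the unedited cells. The 3 libraries labelled wild type held 16920556, 17868966 and 17732606 counts, and the 3 labelled knockout held 16518838, 21127803 and 20929504. Between 23049 and 23999 of 57905 listed genes had at least 1 count in a library. Values are CPM, counts scaled by each library's total and its TMM factor, given as mean ± SD with n = 3 libraries per group. No source used here says that the libraries of a group came from separate cultures, so p-values measure only the spread between these samples. Nor do the labels say whether the edited cells were a clone or a pool, and an effect of the knockout cannot be separated from a difference between clones.

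The targeted gene was measured first. RABIF (ENSG00000183155, chromosome 1, 202848085 to 202858263, minus strand, GRCh37) stood at 9.84 ± 0.54 CPM in the libraries labelled wild type and at 14.8 ± 0.21 CPM in those labelled knockout. The counts were 158, 175 and 185 against 247, 307 and 306, so every library labelled knockout lay above every library labelled wild type. The log2 fold change was 0.58 with a standard error of 0.099 (edgeR adjusted p = 1.8e-06). The target transcript thus went against the label. A frameshift made by Cas9 need not lower the transcript, and gene-level counts do not show whether the coding sequence was cut. Each direction given here therefore follows the labels as deposited, and the libraries are called labelled knockout and labelled wild type throughout.

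Across the transcriptome, 3356 of 15445 tested genes were higher in the libraries labelled knockout and 3369 were lower at an edgeR adjusted p under 0.05. Most shifts were small, with 74.6% of the calls under 1.5-fold. Among the calls of at least 2-fold the balance was uneven, with 587 genes higher and 119 lower. The groups did not overlap for 50.8% of tested genes, against 10% by chance for 3 against 3. Correlations of log2 CPM were at least 0.993 within a group and at most 0.982 between groups, and the first principal component, with 64.8% of the variance, separated the groups.

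The largest rises in the libraries labelled knockout were those of LGI4 (5.16), LGALS14 (4.69) and PNCK (4.50) on the log2 scale. ARG1, the urea cycle arginase (chromosome 6, 131894284 to 131905472), went from 4.85 ± 0.21 to 74.9 ± 5.89 CPM, a log2 fold change of 3.95 with a standard error of 0.082 (edgeR adjusted p = 2.8e-43). EPO, which encodes erythropoietin (chromosome 7, 100318423 to 100321323), rose from 0.82 ± 0.37 to 10.98 ± 1.18 CPM, a log2 fold change of 3.74. PCK1, the cytosolic gluconeogenic PEP carboxykinase, rose by 3.62, the apolipoprotein gene APOA4 by 3.41 and the insulin-like growth factor binding protein gene IGFBP1 by 3.25 on the log2 scale. The inter-alpha-trypsin inhibitor chain gene ITIH3 (3.50) and PDE4C (3.30) completed the 10 largest rises. Each of these genes except ARG1 and APOA4 averaged under 1 CPM in the libraries labelled wild type, so their folds rest on few counts there. Without replicate 2 labelled wild type, LGI4 stood at 6.28 and IGFBP1 at 4.33, so that library set much of both folds. The strand setting of the counting is not given in the sources used here, and ARG1 overlaps MED23 and PNCK overlaps SLC6A8 on the opposite strand.

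The largest falls were of low-level transcripts. HBE1, the embryonic beta-like globin (chromosome 11, 5289582 to 5526847), had 400 counts over the libraries labelled wild type and 0 over those labelled knockout, a fall of 148.7-fold against a floor of 3 counts over the group, with an exact 95% lower limit of 120. HBG2, a fetal globin whose annotated span overlaps that of HBE1 and whose copy HBG1 is near identical, had 182 counts against 2, a ratio of 101.5 with an exact 95% counting interval from 27.7 to 844. MSN, which encodes the membrane-cytoskeleton linker moesin, had 101 counts against 2, a ratio of 56.3 with an interval from 15.2 to 471. Such intervals and floors cover counting error only. The hexokinase gene HK1 fell by 2.49 on the log2 scale, from 2.62 ± 0.19 to 0.45 ± 0.19 CPM. The metallothionein gene MT1M (-3.28), CPED1 (-3.06), the aldo-keto reductase gene AKR1B10 (-2.59), the amino acid transporter gene SLC7A8 (-2.50), CER1 (-2.41) and the adhesion molecule gene L1CAM (-2.22) made up the rest. Single libraries set much of 3 of the falls, as MT1M stood at -5.08 without replicate 2 labelled knockout, and without replicate 3 labelled knockout, which held both MSN counts of that group, CPED1 stood at -4.62 and MSN at -8.12 against -5.56. MT1M and AKR1B10 have near-identical relatives that can share reads, and L1CAM overlaps ARHGAP4 on the same strand.

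Glycolysis genes were higher on balance in the libraries labelled knockout. Of 29 tested members of the glycolysis list, 18 rose, 6 fell and 5 did not pass the test, with the same counts adjusted over the list alone. The median log2 fold change was 0.16 (limma's camera with a preset correlation, adjusted p = 1.9e-06), and adjusted p = 0.094 with an estimated correlation. The regulatory kinase gene PFKFB4 rose most, from 16.0 ± 2.23 to 63.7 ± 3.81 CPM, a log2 fold change of 1.99. The lactate exporter gene SLC16A3 rose by 1.26, the aldolase gene ALDOC by 1.39, the liver phosphofructokinase gene PFKL by 0.71 and the glucose transporter gene SLC2A1 by 0.32. LDHA, the main lactate dehydrogenase gene here (chromosome 11, 18415935 to 18429972), rose from 729 ± 12.9 to 935 ± 25.8 CPM, a log2 fold change of 0.36 with a standard error of 0.035 (edgeR adjusted p = 4.9e-13). PKM had a log2 fold change of 0.02 (edgeR adjusted p = 0.64) and GPI one of -0.02 (edgeR adjusted p = 0.70).

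**Figure D1:**
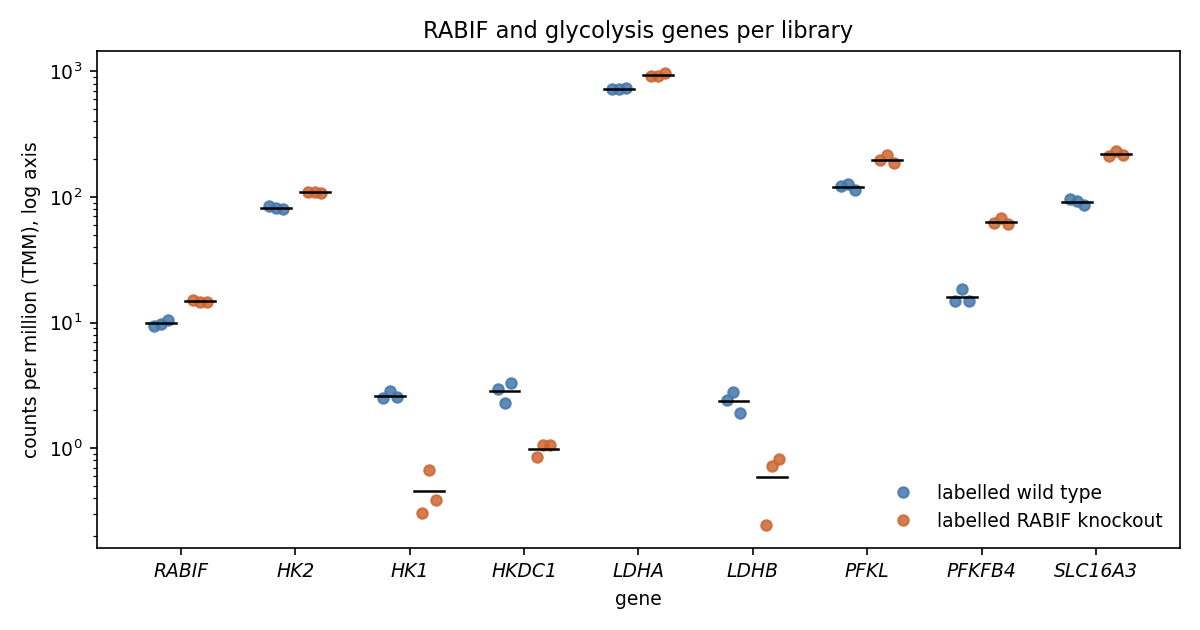
Each point is 1 library and each black bar the mean of 3, in TMM-scaled CPM on a log axis, for RABIF and 8 glycolysis genes. RABIF, HK2, LDHA, PFKL, PFKFB4 and SLC16A3 lie higher in the libraries labelled knockout, while HK1, HKDC1 and LDHB lie lower and under 4 CPM in every library.

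Within enzyme families the abundant and the scarce isozymes moved apart. HK2 (chromosome 2, 75061108 to 75120486) rose from 81.9 ± 2.82 to 109 ± 1.13 CPM, a log2 fold change of 0.41 with a standard error of 0.049 (edgeR adjusted p = 3.2e-10). HK1 fell by 2.49 and HKDC1, a further hexokinase gene, fell by 1.52 on the log2 scale. The 3 hexokinase transcripts together stood at 87.4 ± 2.7 CPM in the libraries labelled wild type and 110.4 ± 1.2 in those labelled knockout, and HK2 made up 93.7% ± 0.52 and 98.7% ± 0.25 of them. LDHB fell by 1.94, from 2.38 ± 0.44 to 0.59 ± 0.31 CPM, while LDHA supplied 99.7% and 99.9% of the lactate dehydrogenase counts. PFKP fell by 1.84 from 1.06 ± 0.51 CPM. That call was lost with limma on log2(FPKM + 1) without a filter (adjusted p = 0.12, with 0.00018 to 0.12 over 13 alternatives). Among the 22 members with a mean of at least 10 CPM, a limit chosen after seeing the data, 15 rose and 2 fell. HBE1 and HBG2, markers of erythroid cells, were lower in the same group as HK1, HKDC1, LDHB and PFKP. These 2 globin genes stood at 7.60 ± 0.21 and 3.46 ± 0.25 CPM in the libraries labelled wild type. A source shared with them was not tested for HKDC1 and PFKP.

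Mitophagy genes moved in both directions. Of 32 tested members of the mitophagy list, 9 rose, 12 fell and 11 did not pass the test, with the same counts adjusted over the list alone. The median log2 fold change was -0.03, the mean was 0.02, and the list did not stand apart from other genes (limma's camera, adjusted p = 0.81). The receptor genes BNIP3 and BNIP3L, also members of the hypoxia list, rose from 55.6 ± 4.11 to 88.7 ± 2.42 CPM and from 31.7 ± 3.15 to 48.9 ± 3.51 CPM, log2 fold changes of 0.67 and 0.63. The cargo receptor gene NBR1 rose by 0.45 and the initiating kinase gene ULK1 by 0.29. SQSTM1, which encodes the cargo receptor p62, fell by 0.37, from 604 ± 6.97 to 467 ± 10.5 CPM (edgeR adjusted p = 2.6e-13), and the mitochondrial phosphatase gene PGAM5 fell by 0.32. PINK1, the kinase gene of the PINK1-Parkin pathway, had a log2 fold change of -0.01 (edgeR adjusted p = 0.94), STOML2 one of -0.02 and FUNDC1 one of -0.15 (edgeR adjusted p = 0.21, with 0.025 to 0.39 over 18 alternatives). The protease gene PARL had a log2 fold change of -0.16 (edgeR adjusted p = 0.025). Its call was lost without replicate 1 labelled wild type (adjusted p = 0.096) and without replicate 2 labelled knockout (adjusted p = 0.18). The range was 0.014 to 0.18 in 18 alternatives, of which 7 changed the call.

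Autophagy, lysosome and Rab genes shifted little as groups by camera. Of 31 autophagy genes 5 rose and 8 fell (camera adjusted p = 0.57), ATG2B by 0.41 and ATG2A by 0.30 upward and ATG16L1 by -0.22. Only 4 fell without replicate 1 labelled wild type, and 5 fell without replicate 2 of either group. Of 35 lysosome genes 9 rose, or 10 adjusted over the list alone, and 11 fell. The protease gene CTSD rose by 0.26, and the membrane protein genes LAMP1 and LAMP2 fell by 0.21 and 0.24. That list's median and mean were both 0.02, while camera put it down (adjusted p = 0.90) and limma's fry up (adjusted p = 0.57). Of 46 Rab GTPases and regulators 10 rose and 18 fell, with a median of -0.10 (camera adjusted p = 0.19). By fry the Rab list shifted down (adjusted p = 0.014). Its adjusted p by camera or fry ran from 0.0075 to 0.38 over 20 alternatives, of which 2 changed the call. Without replicate 1 labelled wild type 11 fell, and without replicate 3 labelled wild type 6 rose and 12 fell. RAB31 and the escort protein gene CHML each fell by 0.52, while MICALL2 rose by 0.55 and the GTPase-activating protein gene TBC1D1 by 0.33. RAB8A, a known binding partner of the RABIF protein, had a log2 fold change of -0.16 (edgeR adjusted p = 0.020). That call was lost without replicate 1 labelled wild type (adjusted p = 0.059) and without replicate 3 labelled knockout (adjusted p = 0.084), the upper end of a range from 0.014 over 18 alternatives. RAB10 at -0.10 (edgeR adjusted p = 0.084) and RAB13 at -0.07 (edgeR adjusted p = 0.38) did not pass the test.

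Hepatocyte genes rose together in the libraries labelled knockout. Of 35 tested hepatocyte secreted and identity genes, 32 rose and 1 fell, and 12 rose at least 2-fold. The median log2 fold change was 0.76 (camera adjusted p = 1.3e-70, and adjusted p = 0.0056 with an estimated correlation). Transferrin (TF) rose from 1867 ± 19.9 to 4955 ± 124 CPM, apolipoprotein A1 (APOA1) from 426 ± 15.5 to 1224 ± 17.6 CPM, fibrinogen beta (FGB) from 991 ± 14.9 to 2545 ± 76.9 CPM and fetuin A (AHSG) from 264.5 ± 9.06 to 926 ± 47.8 CPM. The log2 fold changes were 1.41, 1.52, 1.36 and 1.81.

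Hypoxia-response genes rose as well, with 19 of 26 higher, or 20 adjusted over the list alone, and 1 lower. The median was 0.51 (camera adjusted p = 6.3e-16, and adjusted p = 0.053 with an estimated correlation). NDRG1 rose from 175 ± 9.36 to 547 ± 28.6 CPM, a log2 fold change of 1.65, the mTORC1 inhibitor gene DDIT4 rose by 1.05 and the lysyl oxidase gene LOX by 0.73. Outside the hypoxia list, 26 glycolysis members were tested, of which 15 rose and 6 fell.

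Lipid genes were also higher on balance. Of 25 cholesterol synthesis and uptake genes, 20 rose, or 22 adjusted over the list alone, and 0 fell at an edgeR adjusted p under 0.05. The median was 0.27 (camera adjusted p = 2.7e-09, and adjusted p = 0.032 with an estimated correlation). TM7SF2 rose by 1.08 and LSS by 0.44 on the log2 scale. Of 20 fatty acid synthesis and storage genes 14 rose and 2 fell, with a median of 0.40 (camera adjusted p = 2.0e-11, and adjusted p = 0.084 with an estimated correlation). The carbohydrate-responsive transcription factor gene MLXIPL rose by 2.49, the acetyl-CoA synthetase gene ACSS2 by 0.97 and the desaturase genes FADS1 and SCD by 0.77 and 0.69. Of 21 fatty acid oxidation genes 10 rose and 2 fell, with a median of 0.12 (camera adjusted p = 1.2e-05, and adjusted p = 0.053 with an estimated correlation). CPT1A, the entry step of mitochondrial oxidation, rose from 45.0 ± 4.78 to 127 ± 13.5 CPM, and PPARA and FABP1 rose by 0.98 each.

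Mitotic genes fell nearly without exception in the libraries labelled knockout. Of 33 tested G2/M and mitosis genes 32 fell and 0 rose at an edgeR adjusted p under 0.05, with a median of -0.52 (camera adjusted p = 2.5e-29, and adjusted p = 0.072 with an estimated correlation). CCNB1, the mitotic cyclin, fell by 0.77, from 172 ± 6.85 to 101 ± 4.87 CPM, and CDC20, CENPF and TPX2 fell by 0.75, 0.67 and 0.56. DNA replication genes showed no such shift. Of 34 members 5 rose, 3 without replicate 1 labelled knockout, and 6 fell, with a median of -0.01 (camera adjusted p = 0.63). POLE rose by 0.23, and RRM2, CDC6 and MCM7 fell by 0.20, 0.23 and 0.16. Of 12 replication-dependent histone genes 1 rose and 6 fell (camera adjusted p = 0.050). Leaving out replicate 1 labelled wild type (adjusted p = 0.023) or replicate 1 labelled knockout (adjusted p = 0.045) put that list past the threshold. Its adjusted p by camera or fry ran from 0.00075 to 0.24 over 20 alternatives, of which 11 changed the call. Of 20 p53 targets 5 rose and 6 fell, 3 without replicate 2 labelled wild type (camera adjusted p = 0.81). The cell cycle inhibitor gene CDKN1A rose by 0.68 and TP53INP1 by 0.66, while the stress cytokine gene GDF15 fell by 0.77.

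Oxidant-defence, amino acid and chaperone genes fell on balance. Of 22 NRF2 targets 17 fell and 3 rose, with a median of -0.37 (camera adjusted p = 5.8e-08, and adjusted p = 0.053 with an estimated correlation). NQO1 fell by 0.54, from 820 ± 12.8 to 565 ± 20.3 CPM, the thioredoxin reductase gene TXNRD1 by 0.59 and ME1, also on the fatty acid synthesis list, by 0.71. Of 26 ATF4 targets 16 fell and 4 rose, with a median of -0.16 (camera adjusted p = 0.0014, and adjusted p = 0.072 with an estimated correlation). The amino acid transporter genes SLC7A5 and SLC7A1 fell by 0.99 and 0.66, and DDIT4, shared with the hypoxia list, rose. Of 23 heat shock and immediate early genes 13 fell, or 15 adjusted over the list alone, and 1 rose, with a median of -0.20 (camera adjusted p = 1.4e-05, and adjusted p = 0.094 with an estimated correlation). HSPH1 and MYC fell by 0.65 and 0.66 and HSP90AA1 by 0.42. Of 22 unfolded protein response genes 11 fell, or 12 adjusted over the list alone, and 2 rose (camera adjusted p = 0.088), among them HSP90B1 at -0.29 and XBP1 at 0.23.

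Mesenchymal and matrix genes fell more often than they rose. Of 26 tested, 15 fell, or 16 adjusted over the list alone, and 6 rose, with a median of -0.23 (camera adjusted p = 1.4e-04, and adjusted p = 0.094 with an estimated correlation). The actin-binding protein gene TAGLN fell by 1.85, from 51.1 ± 2.61 to 14.1 ± 1.99 CPM, and the matricellular genes CYR61 and CTGF, both known YAP targets, fell by 0.99 and 0.66. Of 6 tested fibroblast and endothelium markers 3 fell and 0 rose at an edgeR adjusted p under 0.05 (camera adjusted p = 0.018, and adjusted p = 0.13 with an estimated correlation), with the proteoglycan gene LUM at -1.30. Of 3 tested blood markers LYZ fell by 0.62 and CD14 had a log2 fold change of 0.76 (camera adjusted p = 0.20). The CD14 call (edgeR adjusted p = 0.026) was lost without replicate 3 labelled wild type (adjusted p = 0.13) and without replicate 1 labelled knockout (adjusted p = 0.080). The range was 0.017 to 0.13 in 14 alternatives, of which 4 changed the call. Of 9 markers of other epithelial lines 4 rose and 2 fell (camera adjusted p = 0.084), with CDX2 at 1.03 and LIN28B at -0.29.

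Respiratory-chain genes were slightly lower in the libraries labelled knockout. Of 61 nuclear oxidative phosphorylation genes 30 fell, or 32 adjusted over the list alone, and 3 rose, with a median of -0.12 (camera adjusted p = 0.0029, and adjusted p = 0.38 with an estimated correlation). A single gene rose without replicate 1 or 2 labelled knockout, or without replicate 2 or 3 labelled wild type. Cytochrome c (CYCS) fell by 0.27 and the complex I genes NDUFB4 and NDUFS5 by 0.33 and 0.26. Of 13 protein-coding genes of the mitochondrial genome 8 fell and 2 rose, with a median of -0.17 (camera adjusted p = 0.013, and adjusted p = 0.38 with an estimated correlation). MT-ND2 fell by 0.35 and MT-ND3 by 0.36, and MT-ATP6 by 0.28 and MT-ND4 by 0.25, although after quantile normalization of FPKM the last pair stood at 0.02 and 0.00. The list's call also ended with limma on FPKM under 4 settings or an estimated correlation, over a range of 0.00072 to 0.38 in 20 alternatives.

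Of 28 mitochondrial dynamics and biogenesis genes 3 rose and 13 fell (camera adjusted p = 0.13), and 5 rose without replicate 3 labelled knockout. The fusion gene MFN1 fell by 0.51 and the fission gene DNM1L by 0.31, while MIEF2 rose by 0.49. Of 27 tricarboxylic acid cycle and associated genes 4 rose and 7 fell, with 4 falling without replicate 3 labelled wild type or replicate 2 labelled knockout. That list's median of -0.03 and camera direction (down, adjusted p = 0.89) differed in sign from its mean of 0.12 and from fry (up, adjusted p = 0.72), and PCK1 held the largest rise in it. Of 56 ribosomal protein genes 11 fell, or 9 adjusted over the list alone, and 1 rose, which was RPL3 at 0.14, and after quantile normalization of FPKM RPL3 stood at -0.02. The ribosomal list did not pass (camera adjusted p = 0.088). It did without replicate 1 (adjusted p = 0.044) or replicate 2 labelled wild type (adjusted p = 0.017). Its adjusted p by camera or fry ran from 0.0022 to 0.82 over 20 alternatives, of which 6 changed the call. Without replicate 3 labelled wild type 2 ribosomal genes rose and 6 fell. Of 23 interferon-stimulated genes 10 rose and 2 fell (camera adjusted p = 0.088), with IFITM3 at 1.07, STAT2 at 0.73 and USP18 at -0.55. The number that rose was 6 without replicate 1 of either group and 5 without replicate 2 labelled knockout. The median was 0.27 over all tested interferon-stimulated genes. Among the 7 with a mean of at least 10 CPM, 2 rose and 2 fell, with a median of -0.03.

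**Figure D2:**
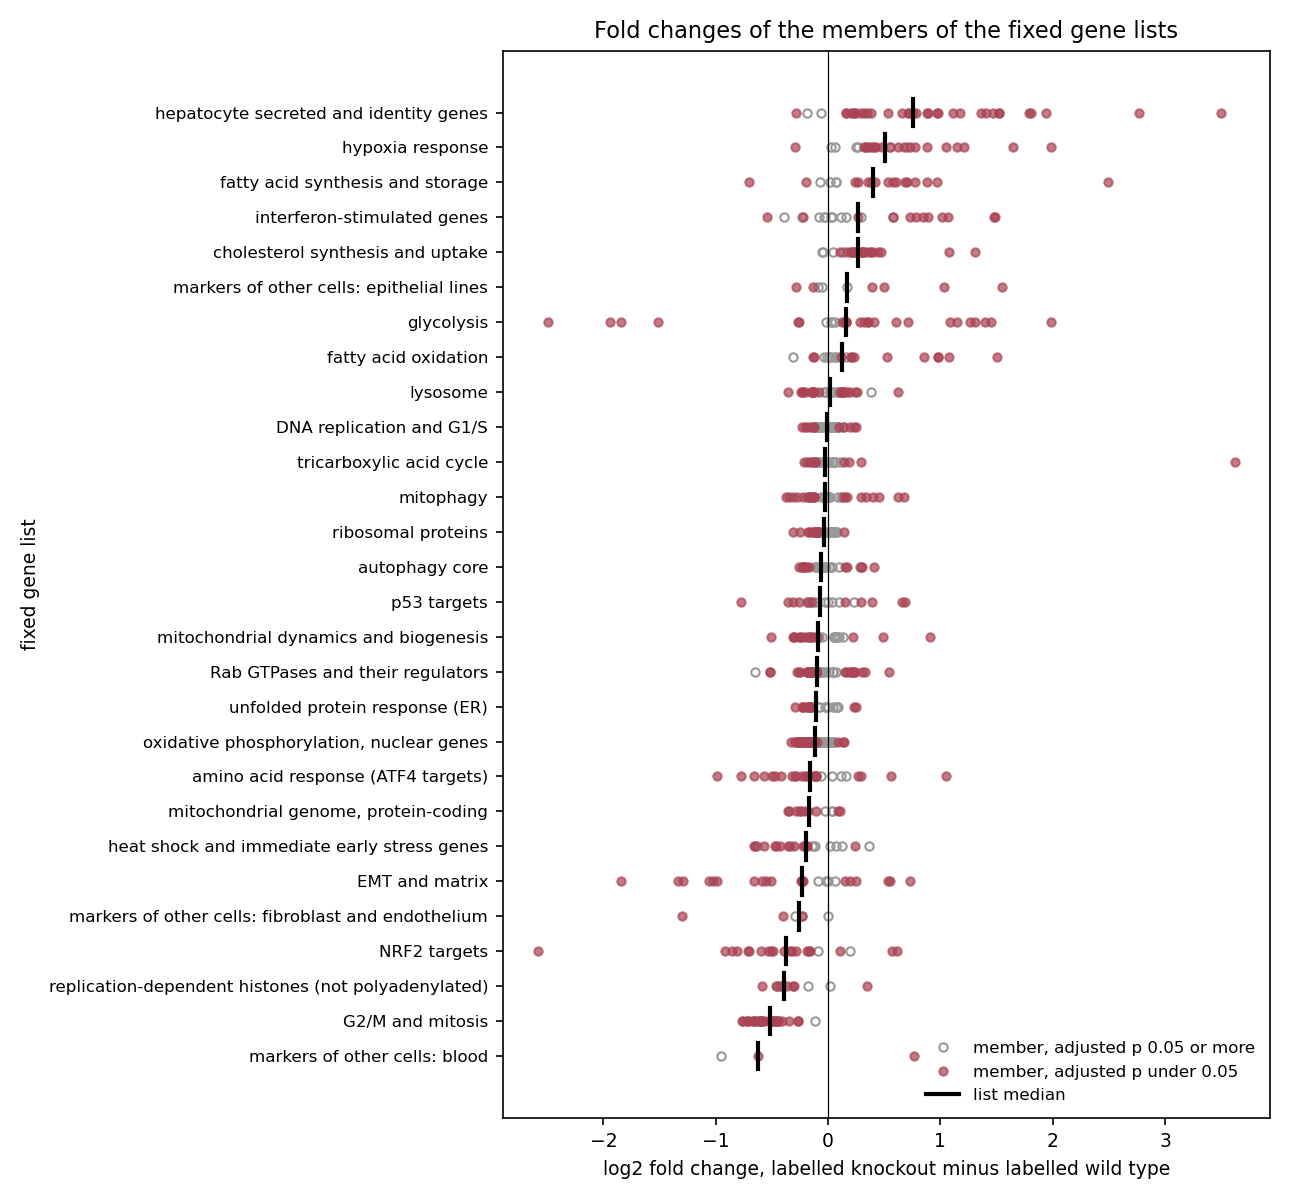
Each point is the log2 fold change, labelled knockout minus labelled wild type, of 1 tested member of 1 of 28 gene lists, filled where the edgeR adjusted p was under 0.05, and each black bar is a list's median. The hepatocyte list has a median of 0.76 and the G2/M list one of -0.52, while the mitophagy list lies at -0.03. After quantile normalization of FPKM, which is not plotted, MT-ATP6, MT-ND4 and RPL3 lose or turn their direction.

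In all, 14 of the 28 lists shifted by camera with a preset correlation, 6 up and 8 down, and the hepatocyte and cholesterol lists also passed with an estimated correlation. By fry, which does not compare a list with other genes, 21 of the 28 lists shifted.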

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

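The limit of 10 CPM on list members was chosen after seeing the data, and the other alternatives before. RABIF stayed higher in the libraries labelled knockout in all 18 alternatives, with adjusted p from 8.6e-08 to 0.0017. With 1 library left out its log2 fold change was 0.55 to 0.62, the glycolysis median 0.14 to 0.24, the mitophagy median -0.05 to -0.02, the genes higher 2924 to 3165, the genes lower 2893 to 3165 and the shifted lists 14 to 16. The genes higher and lower numbered 2107 and 2185 with limma on log2(FPKM + 1) without a filter, and 587 and 119 with a 2-fold limit. DESeq2 called 2454 and 2798, of which 5199 were among the 6725 calls. With an estimated correlation the glycolysis median of 0.16 had adjusted p = 0.094, and 2 lists stayed shifted. For each of the 14 shifted lists that was the highest adjusted p of its alternatives. Restricted to members with at least 10 CPM, the glycolysis median was 0.22 and the mitophagy median -0.03.

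After quantile normalization of FPKM the directions of MT-ATP6 (0.02), MT-ND4 (0.00) and RPL3 (-0.02) were lost or turned. That scaling gives genes of equal rank the same value in every library. A gene that keeps its rank in every library must then show no change, so this setting cannot speak against a change in such a gene. Whether these genes kept their ranks was not tested. No scaling moved the median of all genes beyond -0.034. Over the named genes, 1595 of 1623 alternatives gave the same direction and side of the threshold, 19 lost the call, 6 gained one and 3 turned. With 1 library left out, 834 of 840 were the same and 6 lost the call, in PARL, RAB8A and CD14. For the 26 other lists 315 of 359 alternatives were the same, 17 lost the call and 27 gained one. Low counts limit the folds of genes under 1 CPM in a group.

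The replicate numbers did not pair the libraries, as deviations of same-numbered libraries correlated at 0.002, -0.003 and 0.028, and not every library correlated best with its own number. With the replicate number as a block, 3435 genes were higher and 3429 lower, RABIF stood at 0.58, the glycolysis median at 0.16, the mitophagy median at -0.03, and 14 lists shifted.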

Other observations

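Gene ontology terms, from the annotation in the deposited table, were tested for enrichment among the genes changed at least 2-fold, a test chosen after seeing the data. Against 10575 annotated genes and 1334 terms, 28 terms passed for the 387 higher genes and 2 for the 96 lower ones (Fisher's exact test, Benjamini-Hochberg adjusted). Classical complement activation held 13 of its 23 genes among those higher in the libraries labelled knockout (exact test, adjusted p = 1.9e-10), among them C8B, which rose from 1.84 ± 0.49 to 13.3 ± 1.32 CPM, and C4A and C4B, near-identical copies that can share reads. Fibrinolysis held 7 of 16, sodium ion transport 13 of 41, triglyceride metabolism 8 of 25 and xenobiotic metabolism 13 of 96. Cellular iron ion homeostasis held 7 of 53 and did not pass (exact test, adjusted p = 0.13). Of 3 genes picked after their values were seen, the hepcidin gene HAMP rose from 2.41 ± 0.29 to 13.7 ± 0.52 CPM, the transferrin receptor 2 gene TFR2 from 28.5 ± 2.72 to 142 ± 4.61 CPM and the ceruloplasmin gene CP from 59.4 ± 4.61 to 165 ± 7.12 CPM (SD, n = 3).

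Among the lower genes, negative regulation of growth held 7 of 13, and all 7 were metallothioneins, which bind zinc and copper. Each of the 7 tested metallothionein genes fell, with a median log2 fold change of -1.85, although these close relatives can share reads. Neural crest cell migration held 4 of 21 (exact test, adjusted p = 0.023), with ERBB4, NRP2, OVOL2 and ZEB2. Of these, ERBB4, OVOL2 and ZEB2 averaged 1.10, 0.80 and 1.48 CPM in the libraries labelled wild type, so their falls rest on few counts.

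Of the tests that follow, those of exchanged labels, of a gained segment of a few genes at RABIF and of erythroid RNA as a source of HK1, LDHB and MSN were chosen only after the result was seen. The test of a gained segment around RABIF was narrowed to one of several Mb after its result was seen. The test of foreign RNA first covered HBE1, HBG2, MSN, HK1 and LDHB together and was divided into separate patterns after its result was seen. The erythroid, non-hepatic and YAP gene lists were written after the genes had been tested and before their own values were looked at.

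RABIF was higher in the libraries labelled knockout. A gained segment of several Mb around the gene was argued against, since the 84 tested genes within 5 Mb had a median log2 fold change of 0.012 (bootstrap interval -0.083 to 0.096), with 21 higher and 21 lower. The test of a gained segment of a few genes at RABIF did not decide. Of the 10 nearest tested genes 3 were higher at an edgeR adjusted p under 0.05. They were RP11-480I12.5 by 0.58, CYB5R1 by 0.22 and PPFIA4 by 2.82 on the log2 scale. KLHL12 (-0.08), the nearest, ADIPOR1 (0.08) and TMEM183A (-0.06) did not pass, and all lie nearer than PPFIA4. The nearest genes thus showed no shared rise, but a gain of RABIF with fewer neighbours cannot be excluded. Exchanged labels of the groups could also give the RABIF log2 fold change of 0.584 and cannot be told apart from a true rise, because gene-level counts hold no independent mark of the edit. A rise of an edited transcript that is no longer translated stays open as a biological explanation and was not tested.

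HBE1 and HBG2 were near absent in the libraries labelled knockout and low in those labelled wild type. RNA of erythroid cells in the libraries labelled wild type, or reads from a library of such cells, may be the source, because 6 of 25 other erythroid genes (HBZ, ALAS2, GATA1, KLF1, GFI1B and HEMGN) had a ratio whose exact 95% interval lay above 2. The most abundant of these were ALAS2, with 24 counts against 1, and HBZ, with 15 against 0. HBQ1, TAL1, MYB, EPB42 and NFE2 had at least 9 counts in the libraries labelled knockout too. HBB, HBD, HBM and ICAM4 had 0 counts in both groups, and HBA1, with 7 counts against 0, had a lower limit of 1.61. Genes with so few counts could not pass the bound of 2, so the 25 genes include some that the test could not judge. Expression of these genes in some unedited Huh7 cells was not tested. For HK1, LDHB and MSN the same source cannot be told apart from a change in the cells, since no library of erythroid cells was used here to compare with the excess of HK1 over that of HBE1, which was 0.29. Another non-hepatic line could not be judged either, with 0 of the 1 listed gene under 1 CPM above the bound. Of the 12 listed genes that the libraries labelled knockout held at 1 CPM or more, ANXA1 had a wild-type to knockout ratio of 2.35 (exact 95% counting interval 2.12 to 2.60) and S100A4 one of 2.55 (1.91 to 3.43), while CD44 went the other way (0.84).

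Mitotic genes fell while hepatocyte and hypoxia genes rose in the libraries labelled knockout. For these lists GC content or gene length bias was argued against, since removing a trend on both left at least 90.7% of each list's median. Over the 15057 tested genes with a GC value, however, log2 fold changes correlated with GC content (Spearman 0.271) and little with length (-0.043). The other lists, among them those with small medians such as glycolysis, were not corrected for either. A denser culture at harvest may account for part of the pattern, as the 18 tested YAP targets outside CTGF and CYR61 had a median log2 fold change of -0.43, with 14 lower and 1 higher (camera p = 1.0e-10, and p = 0.0033 with an estimated correlation). ANKRD1 fell by 1.34 and TGFB2 by 1.35. Loss of RABIF or a difference between clones stays open and was not tested.

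For the count of 6725 genes past the threshold, the 6 libraries allow 10 splits, too few for a share under 0.05. The real split gave 6725 genes and was the only 1 of the 10 to give as many, and the highest of the others gave 0. Each other split mixes the groups, so their difference enters the spread within each set of libraries. Few calls could arise there, and the splits cannot speak for or against chance.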
